A study of Mus musculus with 40 samples.

How the data were processed

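RNA of 40 samples labelled as mouse fetal liver, 1 library each, was read as paired ends of 43 nt from a directional library of polyadenylated RNA, per the labels' protocols. Per the submitters' processing notes, reads were handled with Trimmomatic 0.39, STAR 2.7.3a, Salmon 1.3.0 and DESeq2 1.24 on the mouse build mm10; the role and order of these tools and the counting rules are not given in the sources used here. The deposited file of gene values is a signal scale, not whole counts: the authors had divided read counts by size factors before deposit. This was checked from the values, since median-ratio factors recomputed from the table were 1 in all 40 libraries. Taking the smallest step between low values as 1 read, only 26.6 to 57.8% of a library's values came out as whole multiples of it (tolerance 0.1 of a step), so reads could not be recovered. From those steps, depth per library was estimated, in units of 1000000 reads, at 10.5 to 22.6. Precision rests on the spread between libraries, because no counts were at hand.

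The authors also deposited 4 tables of their own folic acid comparisons, with a log2 fold change, a p-value, an adjusted p-value and a mean normalized count per gene as a signal. Their mean count showed which libraries went in. For control diet females, it matched the mean of the 10 libraries poorly (SD of the log2 ratio over genes 0.408) and that without CD replicate 4 and CDF replicate 5 well (0.0411, next best pair 0.249). For the other 3 tables all 10 libraries matched (0.0303 to 0.0395).

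The table held 20593 genes. Symbols came from the file, coordinates from the GENCODE annotation of the same build, in which 20563 gene IDs were found. Genes with a value of at least 10 in at least 5 libraries were tested, 15598 with all 40 libraries. Values were taken as log2(value + 1) and fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 40 libraries, a mean-variance trend and robust moderation. Adjusted p-values are Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05. A log2 difference on this scale understates the change of genes with low values. The plan fixed before the data were examined had been a count model; it was replaced because the values are not counts. Fixed at the same time were 8 comparisons between 2 groups, the sex difference over the 4 diets, 5 differences of effects, and 47 gene lists, of which 46 had at least 3 tested members.

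Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Genes named for a comparison are those past the threshold, or, with fewer than 3 in a direction, the 3 with the smallest p in that direction, given as values that did not pass; some genes this rule names are not reported here. Members named as examples of a list or of the authors' tables were chosen after their values were seen, as were the lists described, which are among those called by camera both with 40 and with 38 libraries, or are named as called with 38 alone. On data simulated as 40 libraries from the spread within groups of the 38 libraries, so without the 2 of low albumin, 15348 genes passed the filter, and the test of WDF against WD males recovered 26.9% of 67 genes changed 1.5-fold, 73.1% of 67 changed 2-fold and 97% of 66 changed 4-fold, with 7 false among 138 calls. The changed genes were drawn only from genes with higher mean values, which favours recovery. The 2 libraries of low albumin widen the spread of the real 40-library fit, so these shares are likely too high for it. On simulated data with no change, 0 lists were called. Each gene was simulated independently of the others, so this does not test whether the preset correlation is adequate.

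Column names of the table match sample titles, apart from 1 female CDF column that lacks the sex letter and was assigned as the remaining title of that diet and number. Libraries were compared before averaging: the highest correlation between any 2 was 0.982, so none was treated as a copy of another. Alternatives fixed beforehand were upper-quartile and recomputed median-ratio scaling, no filter and a stricter filter, limma-voom, fits of the compared groups or of 1 sex alone, a replicate block, an erythroid covariate, a threshold of 0.1 or 1.5-fold, and leaving out each library. Added after seeing the data were fits without the 2 low-albumin libraries (38), without 3 or 4 libraries, library weights, trimmed-mean scaling, pseudocounts of 0.5 and 5, and residual components as covariates. Lists of 18 lung and 14 heart genes were written after 4 and 2 of their genes had been looked at.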

Results

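Messenger RNA was measured in 40 samples labelled as liver of C57BL/6 mouse fetuses on gestational day 18.5, shortly before birth, when the liver holds both maturing hepatocytes and blood-forming cells. The dams had eaten 1 of 4 diets for 13 weeks before breeding: a control diet with 10% of its calories from fat (CD) or a western diet with 45% (WD), each with 2 or 10 mg/kg folic acid, the higher dose marked by the letter F (CDF, WDF). Folic acid is the vitamin that carries the carbon units used to make nucleotides and methyl groups. Each of the 8 combinations of diet and fetal sex had 5 libraries. The authors' normalized read counts summed, in units of 1000000, to 8.97 to 27.8 per library, with a median of 17.0. Values below are normalized read counts as group mean ± SD with n = 5 unless another n is given, and log2 differences come from limma on log2(value + 1). The labels name neither dam nor litter, so p-values measure the spread between fetuses, some of which may share a litter. With no change at all, a share of about 0.05 of the tested genes is expected at an unadjusted p under 0.05. Several of the counts given below for 40 libraries lie under that share. Such counts are therefore no evidence of change by themselves.

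Hepatocyte message was high in 38 of the 40 libraries, in which Alb, the gene of serum albumin, lay between 641900 and 1497000. In the other 2 libraries it was 7708 (CD females, replicate 4) and 5278 (CDF females, replicate 5). The same 2 libraries held 101200 and 67010 for Sftpc, the gene of a lung surfactant protein. Sftpc lay above 1000 in 6 further libraries with ordinary Alb, namely CD females replicate 5 (30180), CDF females replicate 4 (24800), WDF males replicate 2 (5978), CD males replicate 5 (4012), WD females replicate 4 (2008) and CDF females replicate 2 (1538). In the remaining 32 libraries it was at most 139.7. CDF females replicate 5 also held 7903 for Myh6, a heart muscle myosin, and CD females replicate 5 held 2920. Because 4 of the 6 highest Sftpc values fall in the CD and CDF females, the counts, lists and gene values of comparisons that use those groups are given with all libraries and again without the 2 low-albumin libraries. The 2 libraries also widen the spread that the 40-library fit applies to every group, males included.

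**Figure D1:**
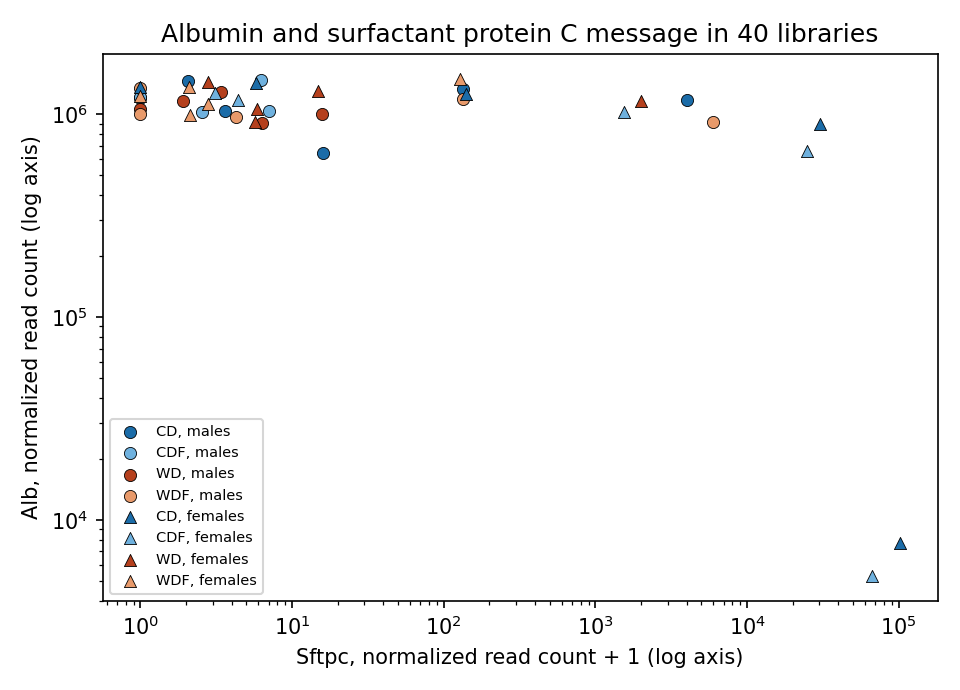
Each point is 1 of the 40 libraries, with the normalized read count of Sftpc plus 1 on the horizontal log axis and that of Alb on the vertical log axis, circles for males and triangles for females, coloured by maternal diet. The 2 female libraries at the lower right hold 7708 and 5278 for Alb, whereas the other 38 libraries lie at 641900 or above.

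Female and male livers differed in genes of the sex chromosomes. Xist, the RNA that silences one X chromosome, was 4930 ± 1490 in the 20 females and 1.88 ± 3.44 in the 20 males (log2 difference 11.20 ± 0.25 SE), and lies on chromosome X from 103460366 to 103483254 in mm10. Higher in females were also Eif2s3x, a translation initiation factor (2740 ± 255 against 1870 ± 192 in males, log2 difference 0.56, adjusted p = 4.41e-09), the histone demethylase Kdm6a (753 ± 252 against 418 ± 137, 0.84, adjusted p = 0.00831) and the non-coding 5530601H04Rik (103 ± 19.9 against 74.6 ± 11.1, 0.45, adjusted p = 0.016). With the replicate number as a block within diet, Kdm6a (adjusted p = 0.143) and 5530601H04Rik (0.0812) no longer passed. The Y-linked Ddx3y, Eif2s3y, Uty, Kdm5d and the non-coding Gm29650 were higher in males, with Ddx3y at 1310 ± 154 against 0.34 ± 0.733. These 9 genes, 4 higher and 5 lower in females, were the ones past an adjusted p of 0.05 by limma among 15598 tested. The list of genes that escape X inactivation was higher in females, with 9 of 9 members in that direction and a median log2 difference of 0.42. Its call held with an estimated correlation between members (adjusted p = 7.76e-10), as did that of the 4 Y-linked genes (adjusted p = 1.98e-15). Sex labels and these genes matched in 40 of 40 libraries.

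The first dietary question was what a western diet does to the fetal liver at the ordinary folic acid dose. In males, genes that make fatty acids were lower in WD than in CD livers, 23 of 24 of them, with a median log2 difference of -0.54. Me1, the malic enzyme that supplies reducing power for fat synthesis, averaged 348 ± 190 in WD and 711 ± 178 in CD males, Thrsp, a regulator of lipogenesis, 39 ± 49.2 against 196 ± 82.4, and the desaturase Scd1 5120 ± 2450 against 8690 ± 2120. The WD mean of Thrsp rests largely on replicate 4 (125, the others 2.74 to 32.8). Genes of cholesterol synthesis were lower in 22 of 24 cases (median -0.35). Cell cycle genes were higher in 28 of 30 cases (median 0.33), among them Ccnb1, the mitotic cyclin B1 (1620 ± 123 against 1060 ± 314), and the replication factor Gins2 (221 ± 42.4 against 132 ± 45.9). By camera, which tests a list against all other genes with a preset correlation of 0.01, the adjusted p was 2.4e-10 for fatty acid synthesis, 0.00572 for cholesterol and 5.27e-11 for the cell cycle. With an estimated correlation the 3 lists gave adjusted p = 0.835, 0.896 and 0.835. The cholesterol call was lost without CD replicate 1 (median -0.26) or WD replicate 5 (-0.24).

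Markers of other cell types moved with these lists in the same males. Those of the mesothelium that covers the liver were lower in 8 of 9 cases (median -0.62, camera adjusted p = 0.0231), those of bile duct cells in 9 of 10 (median -0.55, 0.00572) and those of skeletal muscle in 10 of 13 (median -1.06, 0.00572). With an estimated correlation each of these lists gave adjusted p = 0.835. The bile duct median was -0.84 without CD replicate 1. The mesothelial call was lost without CD replicate 3 (median -0.47) or 5 (-0.52) or WD replicate 2 (-0.41) or 3 (-0.57), and with the erythroid score as a covariate (-0.53), and the muscle call without CD replicate 4 (-0.50). No single gene passed by limma (0 of 15598, 491 at an unadjusted p under 0.05; 0 by limma-voom). The smallest unadjusted p in each direction belonged to Phf19, Wdr70 and Pms2, a mismatch repair gene (WD 244 ± 70.6, CD 145 ± 25.6), and to Lysmd2, Pltp, which transfers phospholipids between lipoproteins (560 ± 159 against 1270 ± 416), and Cpne8. Without the 2 low-albumin female libraries the count was 0, with 1023 genes at an unadjusted p under 0.05. Weighting libraries by how close they lie to their group, a setting added after the data were seen, gave 93 genes past the threshold.

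At the high folic acid dose, WDF males again had lower values than CDF males in both lipid synthesis lists. The fatty acid list was lower in 20 of 24 members (median log2 difference -0.61) and the cholesterol list in 22 of 24 (median -0.53). Me1 averaged 260 ± 80.9 against 767 ± 464, Acly, which makes the acetyl-CoA for fat synthesis, 3410 ± 791 against 7130 ± 2450, Acaca, which makes malonyl-CoA, 804 ± 99.8 against 1360 ± 288, and the squalene epoxidase Sqle 2070 ± 361 against 3240 ± 260. Adjusted over the list alone, 2 members of the fatty acid list passed by limma with 40 libraries and 9 with 38, and for cholesterol 0 and 15. Markers of megakaryocytes, the cells that shed platelets, were higher in 14 of 15 cases (median 0.44) and genes of oxidative phosphorylation in 27 of 29 (median 0.28). Camera gave adjusted p = 1.44e-07 for fatty acid synthesis, 2.52e-06 for cholesterol, 0.0339 for megakaryocytes and 8.01e-05 for oxidative phosphorylation, and with an estimated correlation each list gave adjusted p = 0.985. The megakaryocyte call was lost without any 1 of CDF replicates 1 (median 0.45), 2 (0.36) and 4 (0.34) and WDF replicates 4 (0.44) and 5 (0.35).

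No single gene passed in that comparison either (limma 0 of 15598, 557 at an unadjusted p under 0.05; limma-voom 0; 0 with 38 libraries, 1061 at an unadjusted p under 0.05). Among the genes with the smallest unadjusted p were Cul9 and Slc15a4, higher in WDF, and Trub1, Me1 and the aldehyde oxidase Aox1 (WDF 15.8 ± 6.49, CDF 40.8 ± 11.5), lower in WDF. Me1 lies on chromosome 9 from 86581371 to 86695953 in mm10. Library weights gave 293 genes past the threshold.

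**Figure D2:**
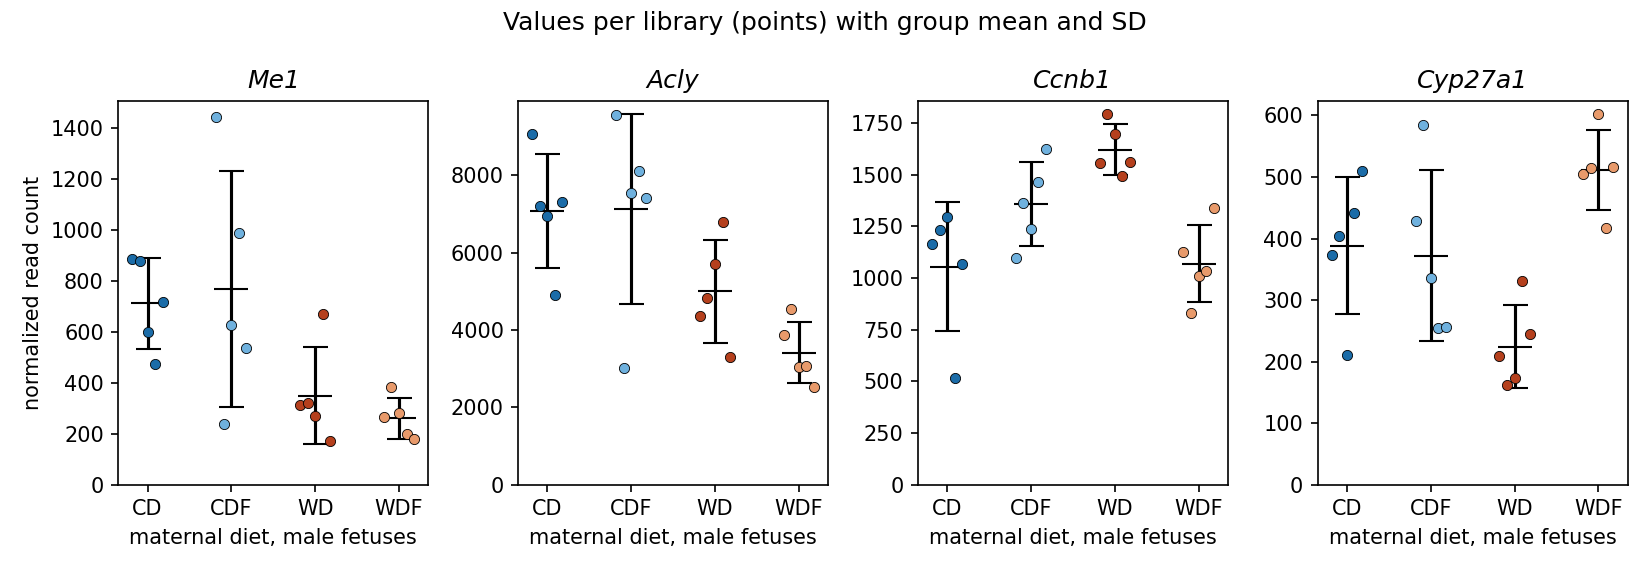
Normalized read counts of Me1, Acly, Ccnb1 and Cyp27a1 are shown for the male fetuses, 1 point per library, with maternal diet on the horizontal axis and bars for the group mean and SD of 5 libraries. Me1 averaged 711 in CD, 348 in WD and 260 in WDF males, and Cyp27a1 averaged 224 in WD and 511 in WDF males; none of the 4 genes passed the test over all genes with 40 libraries.

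In females the western diet comparison at 2 mg/kg rested on a CD group with 1 low-albumin and 1 further lung-rich library. Cell cycle genes were higher in WD than in CD females in 29 of 30 cases (median log2 difference 0.57, and 0.25 without the 2 low-albumin libraries), for example the topoisomerase Top2a (4500 ± 737 against 2830 ± 939, or 3220 ± 429 with n = 4). Red cell genes were higher in 27 of 27 cases (median 1.26, then 0.38), with the erythroid regulator Klf1 at 2040 ± 374 against 1190 ± 678, or 1490 ± 201 with n = 4. Mesothelial markers were lower in 9 of 9 cases (median -1.30, then -0.86), including Msln (210 ± 89.4 against 1100 ± 1320, or 525 ± 411 with n = 4), and clock genes in 16 of 18 (median -0.38, then -0.17), including Npas2 (31.7 ± 11.2 against 88.9 ± 71.3, or 57.4 ± 12.6). Their camera adjusted p with 38 libraries was 3.11e-06, 1.04e-07, 0.000117 and 0.00168, and with an estimated correlation 0.785, 0.742, 0.742 and 0.742. The mesothelial call was lost with 36 libraries, when the 4 highest in Sftpc, the further CD library among them, were left out (median -0.57). The list of fatty acid synthesis was lower in 19 of 23 members with 38 libraries (median -0.40, camera adjusted p = 0.000881, estimated correlation adjusted p = 0.785), and had a median of -0.08 and camera adjusted p = 0.501 with 40. Me1 averaged 356 ± 108 against 660 ± 121, or 657 ± 140 with n = 4, whereas Pnpla3, a lipid droplet enzyme, differed in sign between the fits (0.12 with 40 libraries, -0.89 with 38).

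Over all genes this female comparison gave 0 by limma, with 2710 genes at an unadjusted p under 0.05, 0 by limma-voom, and 0 with 38 libraries, with 1011. Leading genes were Amy2a3, Rpusd4 and the mitotic kinase Nek2, and Spg21, Npas2 and Parp3. The low-albumin CD replicate 4 held 889 for Spg21 (the other CD females 421 to 540) and 252 for Parp3 (34.8 to 54.6). Over 33 alternative settings their log2 differences ran from -0.82 to -0.42 and from -1.72 to -0.72. Amy2a3 is 1 of several near-identical amylase genes and was listed at 0 in all 5 CD females, so its value is uncertain. The 1 gene that passed in a fit of the 10 compared libraries alone is counted with the other settings in the closing section.

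WDF females, set against CDF females, showed lower markers of intestine and stomach (6 of 9 members, median log2 difference -1.10, and -1.16 with 38 libraries). Apoa4, an apolipoprotein of gut and liver, averaged 77.5 ± 41.4 in WDF and 549 ± 522 in CDF females, or 659 ± 532 with n = 4, and Fabp2, the intestinal fatty acid carrier, 59 ± 17.4 against 169 ± 117, or 207 ± 94.9 with n = 4. Skeletal muscle markers were lower in 13 of 13 cases (median -1.75, then -0.83), and red cell genes higher in 27 of 27 (median 1.26, then 0.13), with the membrane protein gene Sptb at 7550 ± 1190 against 4140 ± 3200 (log2 difference 1.56), or 5070 ± 2810 with n = 4 (0.91). Camera adjusted p with 38 libraries was 0.000222, 0.00726 and 0.0389, and with an estimated correlation 0.466, 0.814 and 0.814. With 40 libraries less 1, the intestinal call was lost without CDF replicate 1 (median -0.41), 2 (-1.04), 3 (-0.66) or 4 (-0.56), and the red cell call without CDF replicate 5 (0.13). Me1 averaged 414 ± 109 in WDF and 775 ± 329 in CDF females, or 844 ± 334 with n = 4. The fatty acid synthesis list was lower in 16 of 23 members with 38 libraries (median -0.30, camera adjusted p = 0.0084, estimated correlation adjusted p = 0.814), and had a median of 0.06 and camera adjusted p = 0.898 with 40. By limma 0 genes passed (1194 at an unadjusted p under 0.05), 0 by limma-voom, and 0 with 38 libraries (1252). The smallest p belonged to Phospho1, Glp2r and Ago3, and to Bok, Tes and Mme. The low-albumin CDF replicate 5 held 649 for Mme, and the other CDF females 9.53 to 62.5. In the 28 alternative settings that tested Mme, its log2 difference ran from -5.30 to -3.19.

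The second question was what the high folic acid dose does within each diet. It stood out most in males of western diet dams, where camera called 11 lists between WDF and WD with 40 libraries, 3 of them described here and the other 8 in the closing section. Cell cycle genes were lower in WDF in 27 of 30 cases (median log2 difference -0.30), with Ccnb1 at 1070 ± 186 against 1620 ± 123, the checkpoint kinase Bub1b at 579 ± 67.6 against 802 ± 86.6 and the replication helicase Mcm6 at 2240 ± 187 against 2980 ± 191. Genes of fatty acid oxidation and other targets of PPARα were higher in 28 of 32 (median 0.31), with Acadvl, a mitochondrial oxidation enzyme, at 4580 ± 672 against 3000 ± 336, the fatty acid carrier Fabp1 at 9140 ± 817 against 6350 ± 904 and the carnitine transporter Slc25a20 at 739 ± 53.5 against 557 ± 43.3. Megakaryocyte markers were higher in 15 of 15 (median 0.48), with the clotting factor gene Vwf at 736 ± 187 against 422 ± 45 and the platelet glycoproteins Gp5 and Gp9 at 314 ± 36 against 206 ± 10.6 and 237 ± 37.7 against 159 ± 14.2. Camera adjusted p was 1.7e-06, 0.00398 and 0.0155 for the 3 lists, and with an estimated correlation each gave adjusted p = 0.899. Without WD replicate 2 the oxidation (median 0.30) and megakaryocyte (0.37) calls were lost. Adjusted over the list alone, 0 cell cycle, 0 oxidation and 0 megakaryocyte genes passed with 40 libraries, and 0, 10 and 0 with 38.

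Single genes in that comparison included Cyp27a1, an enzyme of bile acid synthesis (511 ± 65.4 in WDF against 224 ± 67.5 in WD, log2 difference 1.22), the retinol carrier Rbp4 (31300 ± 2580 against 20700 ± 4370), the iron carrier Trf (750000 ± 64900 against 547000 ± 65300), Apoc3, an apolipoprotein of triglyceride-rich particles (1980 ± 1530 against 544 ± 194), the growth factor Igf2 (60100 ± 9370 against 43500 ± 3960) and Igfbp2, which binds such factors (12100 ± 3910 against 4610 ± 3720). By limma 0 of 15598 genes passed (714 at an unadjusted p under 0.05), 0 by limma-voom, and 0 with 38 libraries (1354; smallest adjusted p = 0.105). The smallest p belonged to Slc15a4, Hps4 and Ptpn12, and to Phf19 (43.3 ± 7.35 against 104 ± 38.1), Pms2 (126 ± 26.9 against 244 ± 70.6) and Elp4 (99.9 ± 22.3 against 190 ± 22.7), the last 3 with all 5 WDF libraries below all 5 WD libraries.

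The authors' deposited table for this comparison, made with a count model, called 203 genes at an adjusted p under 0.05, 134 higher and 69 lower. All 203 had the same direction in limma, and 193 of them had an unadjusted p under 0.05 with 38 libraries. The authors called these genes on the same WD and WDF male libraries, so this match was largely fixed in advance. Over all genes, their log2 fold changes correlated with those here at 0.61 with 40 libraries, against 0.18 to 0.25 for their other tables. Tested against the fixed lists with Fisher's exact test, the 203 genes in the authors' deposited table held 6 of 19 hepatocyte markers, all higher (adjusted p = 1.04e-05), 5 of 15 megakaryocyte markers, all higher (adjusted p = 4.14e-05), and 5 of 30 cell cycle genes, all lower (adjusted p = 0.00109). That test takes the genes of a list as independent, and no list held here with an estimated correlation (smallest adjusted p 0.899 with 40 libraries and 0.341 with 38). By camera the hepatocyte list had adjusted p = 0.508 with 40 libraries and 0.00102 with 38 (median 0.18 in both). Their log2 fold change for Cyp27a1 in the authors' deposited table was 1.12 and for Ccnb1 -0.53. Weighting libraries in limma gave 514 genes past the threshold.

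In males of control diet dams camera called 7 lists for the high dose, 6 lower and 1 higher, among them markers of several minor cell types and of skeletal muscle. Mesothelial markers were lower in CDF than in CD males in 9 of 9 cases (median log2 difference -0.58), with Upk3b at 308 ± 67.6 against 512 ± 70.1. Bile duct markers were lower in 9 of 10 (median -0.47), with the keratin Krt7 at 80.9 ± 22.1 against 327 ± 296. That CD mean of Krt7 rests largely on replicate 3 (844, the others 145 to 304). Neutrophil markers were lower in 18 of 19 (median -0.45), with Ngp at 7290 ± 269 against 9970 ± 884 and the iron-binding Lcn2 at 2600 ± 365 against 3890 ± 885. Skeletal muscle markers were lower in 12 of 13 (median -0.97). Camera adjusted p was 0.00108, 0.00793, 0.0374 and 0.00793 for the 4 marker lists, and with an estimated correlation 0.957, 0.95, 0.996 and 0.996. The bile duct call was lost without CD replicate 3 (median -0.40; -0.26 without CDF replicate 2) and the muscle call without CD replicate 1 (-0.84) or 4 (-0.46) or CDF replicate 3 (-0.75). The neutrophil call was lost without any 1 of CD replicates 1 to 4 (-0.46, -0.42, -0.49 and -0.36) and CDF replicates 1, 2 and 4 (-0.52, -0.37 and -0.45). Cell cycle genes were higher in 25 of 30 (median 0.14, or 0.08 without CD replicate 5, camera adjusted p = 0.00108, estimated 0.996), opposite to their direction in western diet males. Immediate early genes were lower in 13 of 15 (median -0.24, 0.0305, estimated 0.957), with the stress factor Atf3 at 47.4 ± 4.2 against 80.4 ± 18.2, and the call was lost without CD replicate 3 (-0.11) or 4 (-0.17) or CDF replicate 2 (-0.23) or 4 (-0.16). Ribosomal protein genes were lower in 33 of 38 (median -0.17, 0.0276, estimated 0.996), and the call was lost without CD replicate 3 (-0.15) or 4 (-0.01) or CDF replicate 4 (-0.12) or 5 (-0.09), with medians of -0.26 without CD replicate 1 and -0.30 without CDF replicate 1. By limma 0 genes passed (254 at an unadjusted p under 0.05), 0 by limma-voom, and 0 with 38 libraries (536). The smallest p belonged to Ccdc148, Wdr70 and Trub1, and to Mn1, Cib2 and Krt14, whose CD mean of 92.6 ± 136 rests on replicate 3 (334). The authors' deposited table called 7 genes, 3 higher and 4 lower, among them Xlr3b and Apoa5 higher and Ngp, Stfa2, Krt7 and Gprc5a lower.

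In females of control diet dams, genes of oxidative phosphorylation were higher in CDF than in CD in 29 of 29 cases (median log2 difference 0.47, and 0.39 with 38 libraries) and ribosomal protein genes in 38 of 38 (median 0.41, then 0.53). Markers of intestine and stomach were higher in 8 of 9 (median 0.70, then 1.18), with Apoa4 at 549 ± 522 against 75.7 ± 51.4, or 659 ± 532 against 93.5 ± 37.5 with n = 4 in each group, and Fabp2 at 169 ± 117 against 47.3 ± 25.2, or 207 ± 94.9 against 58.4 ± 4.64. Clock genes were lower in 16 of 18 (median -0.30, then -0.31), with Per3 at 102 ± 75.4 against 138 ± 83.6, or 70.6 ± 31.1 against 101 ± 15 with n = 4 in each group. Camera adjusted p with 38 libraries was 9.06e-06, 2.55e-14, 0.00132 and 0.00473, and with an estimated correlation 0.909, 0.909, 0.863 and 0.909. With 40 libraries less 1, the ribosomal call was lost without CDF replicate 4 (median 0.10), the intestinal call without CD replicate 4 (0.71) or CDF replicate 1 (0.66) or 3 (0.79), and the clock call without CD replicate 4 (-0.17). The oxidative phosphorylation call was kept but had a median of 0.16 without CD replicate 4 and 0.23 without CDF replicate 4. Other medians that moved by over 1.5 times were the ribosomal (0.67) and intestinal (2.13) ones without CDF replicate 5, the intestinal one without CD replicate 5 (1.33) or CDF replicate 4 (1.18), and the clock one without CDF replicate 4 (-0.14). By limma 0 genes passed (316 at an unadjusted p under 0.05), 0 by limma-voom, and 0 with 38 libraries (1196). The authors' deposited table called 4 genes, all higher, namely Fabp2, Apoa4, Prap1 and Dysf. Among those with the smallest p here were Apoa4, Gemin4 and Lat, and Ap1ar and Nom1. Gemin4 was 0 in CD replicates 3 and 5, an on and off pattern that a copy elsewhere in the genome can give, and is uncertain.

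In females of western diet dams the oxidative phosphorylation, ribosomal protein and clock lists moved the other way, with smaller medians with all libraries. That order of sizes was not tested and could turn without 1 library. On the control diet the medians fell to 0.16 (oxidative phosphorylation, without CD replicate 4), 0.10 (ribosomal) and -0.14 (clock, both without CDF replicate 4). Oxidative phosphorylation genes were lower in WDF than in WD in 27 of 29 cases (median log2 difference -0.23) and ribosomal protein genes in 36 of 38 (median -0.26), whereas clock genes were higher in 15 of 18 (median 0.15), with Per3 at 99.2 ± 6.95 against 69.1 ± 6.68. Camera adjusted p was 1e-05, 2.12e-06 and 0.0338, and with an estimated correlation each gave adjusted p = 0.987. The clock call was lost without WD replicate 2 (median 0.09), 3 (0.14) or 5 (0.08) or WDF replicate 3 (0.21) or 4 (0.07). The ribosomal median was -0.40 without WDF replicate 3 and -0.15 without WDF replicate 4. Among the genes with the smallest p were the DNA repair gene Xrcc4 (108 ± 25.6 against 70.7 ± 16) and Brcc3, and Nr6a1, Homez and the necroptosis kinase Ripk3 (99 ± 24.9 against 150 ± 41.6). By limma 0 genes passed (107 at an unadjusted p under 0.05), 0 by limma-voom, and 0 with 38 libraries (221). The authors' deposited table called 0 genes, with 456 at an unadjusted p under 0.05.

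Genes that carry and use folate were looked at in every comparison, since folic acid was the treatment. Of the 30 tested members of that list, 0 passed adjusted over the list alone and 0 over all genes, in each of the 8 comparisons, with 40 or 38 libraries. As a list they were called higher by camera with 40 libraries in WD against CD females (22 of 30, median log2 difference 0.49, adjusted p = 0.00708) and in WDF against CDF females (23 of 30, 0.23, 0.0134). Neither call held with 38 libraries (medians 0.05 and -0.03, adjusted p = 0.314 and 0.47) or with an estimated correlation (0.637 and 0.546 with 40). For the folic acid dose the member with the smallest p was Mthfd1, a folate-interconverting enzyme, in CD males (CDF 1950 ± 107, CD 1680 ± 211), and Folr1, a folate receptor, in WD males (WDF 4.54 ± 1.18, WD 11.5 ± 3.37). With 38 libraries it was Mthfs in WD females (108 ± 15.8 against 148 ± 26.6). For the western diet it was Mthfd2l in males at 2 mg/kg (WD 55.8 ± 7.85, CD 37 ± 9.5), Slc25a32, the mitochondrial folate carrier, in males at 10 mg/kg (WDF 195 ± 22.4, CDF 287 ± 63.1) and the serine-to-glycine enzyme Shmt2 in females at 2 mg/kg (WD 3260 ± 357, CD 2090 ± 872, log2 difference 0.81, or CD 2470 ± 297 with n = 4, 0.40).

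Whether an effect depended on sex or on the other diet factor was tested as a difference of 2 effects. By limma 0 of 15598 genes passed in each of the 5 such tests, and 0 by limma-voom. Unadjusted p under 0.05 was reached by 466 genes for the folic acid effect by sex on the control diet, 591 on the western diet, 1026 for the folic acid effect by diet in males, 605 in females, and 1187 for the western diet effect by sex. With 38 libraries 0 genes passed in each, with 1378, 1156, 1893, 1983 and 903 at an unadjusted p under 0.05. Library weights gave 603 genes past the threshold for folic acid by sex on the western diet and 351 for folic acid by diet in males.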

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

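The tests of lung and heart markers, of a scale factor, of the diet group and of misassigned reads, and the fits of list differences without 1 library, were chosen after the result was seen, and the limits of the 2 tests of misassigned reads in females were set knowing the values; the 3 tests of the authors' 203 genes were written before their results. Gene groups whose effect differed between sexes or diets are given first. By camera with the preset correlation, with 40 and with 38 libraries, oxidative phosphorylation and ribosomal protein lists differed in each of the 5 tests of a difference. With an estimated correlation none of these, nor of the other differences below, 18 in all, held (adjusted p = 0.73 or above with 40 libraries). The 5 tests share groups, so their results depend on each other and do not count as repeated evidence. Oxidative phosphorylation had median log2 differences of effects of 0.56 for folic acid by sex (females less males) on the control diet, -0.58 on the western diet, 0.44 for folic acid by diet (western less control) in males, -0.70 in females, and 0.68 for the western diet effect by sex. Ribosomal proteins had 0.59, -0.48, 0.40, -0.69 and 0.61 in the same order. The folic acid effect on cell cycle genes differed by sex on the western diet (0.29) and by diet in males (-0.43). In males it also differed by diet for immediate early genes (0.53) and skeletal muscle markers (1.61), and in females for clock genes (0.46). The western diet effect differed by sex for glycolysis (0.64), hepatocyte (1.48) and neutrophil markers (1.46), lists in which the low-albumin CD library stands apart. Without that library (CD females replicate 4) those 3 medians were 0.18, 0.08 and 0.30 and the calls were lost. Of the 18 differences, 12 stayed past the threshold without any 1 library. Lost besides those 3 were oxidative phosphorylation by diet in males without WD replicate 5 (0.31), ribosomal proteins there without WD replicate 4 (0.27), and cell cycle by sex without WD males replicate 2 or WD females replicate 1 (0.20 each). Without CDF females replicate 4, ribosomal proteins had 0.25 by sex on the control diet and -0.35 by diet in females, oxidative phosphorylation 0.33 and -0.46, and clock genes 0.28. Without CD females replicate 4, oxidative phosphorylation had 0.29 by sex on the control diet, -0.45 by diet in females and 0.44 for the western diet by sex, and without CD males replicate 4 ribosomal proteins had 0.23 by diet in males.

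Single libraries far from the other 4 of their group, by the ratio of gap to range, were found in 32 of 246 groups tested, 13%. For normal and independent values chance gives about 1 in 20. Here the values were not log-transformed, and many of the genes had been picked after their values were seen. An excess over chance is therefore not shown. Of the 32, 13 were 1 of the 2 low-albumin libraries. CD females replicate 4 stood apart in its total (9.6, totals in units of 1000000), erythroid score (-4.55), Fabp2 (2.85), Dysf (223), Npas2 (215), Per3 (286), Spg21 (889), Parp3 (252), Klf1 (21.1) and Msln (3380). CDF females replicate 5 did so in erythroid score (-4.60), Npas2 (124) and Mme (649). Among the males, CD replicate 4 had the highest total of its group (20.8), Hba-a1 (1020000) and Lcn2 (5420), CD replicate 3 the highest Krt14 (334) and Krt7 (844), and CD replicate 2 the lowest Mn1 (79.2). CDF males stood out in Ddx3y (replicate 2, 1460) and Ngp (replicate 3, 7750), and WD males in Bub1b (replicate 1, 651), Thrsp (replicate 4, 125) and Fos (replicate 5, 38.7). WDF males did so in the total (replicate 2, 18.4), Fos (replicate 4, 84.7) and Gp9 (replicate 5, 302). In the other females the values were Prap1 7.85 in CD replicate 3, Nr6a1 136 in WD replicate 5 and 31.5 in WDF replicate 3, Sptb 9640 in WDF replicate 2, and a total of 20.4 in WDF replicate 3.

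The 2 libraries with little albumin message may hold lung in place of liver, as a hypothesis. Over 14 lung genes not looked at before, the median was 7.58 and 7.08 log2 units above the other 38 libraries, while 19 hepatocyte markers lay at -7.18 and -7.77, and 8 heart genes at 1.49 and 8.25; 7 of the 18 lung and 3 of the 14 heart list genes had a median of at least 10 in the 32 libraries with little Sftpc. A single scale factor is excluded, since the lung and hepatocyte medians lay at least 14.76 log2 units apart, and an effect of the diet groups is excluded, since 8 of the other 8 libraries of those groups had Alb at or above the lowest value of the remaining 6 groups.

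In the 6 further libraries, lung genes stood at least 0.5 log2 units above the remaining 32 in 6 of 6 (medians 1.78 to 5.52; heart medians 7.27 in CD females replicate 5 and 2.70 in CDF females replicate 4), and misassigned reads from the low-albumin females are excluded for the 2 males among them, since Xist there reached at most 0.00425 of the amount needed (0.51 and 0.659, against 120 and 179 needed). As the only source they are also excluded for CDF females replicate 4, where 17 lung genes reached a median of 0.15 of the amount its Sftpc needed, and for the heart message of CD females replicate 5, where 4 of 13 heart genes lay above their values in both supposed sources. Misassigned reads stay open for the lung message of CD females replicate 5, CDF females replicate 2 and WD females replicate 4 (medians 0.56, 1.52 and 0.97 of the amount needed). Neighbouring tissue taken at dissection stays open for all 8 libraries, and no dissection record was used here. It was not tested as a source of the shifts in intestine, stomach and skeletal muscle markers.

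The authors' 203 genes for folic acid in western diet males had a median change of 0.68 log2 units in the called direction with 38 libraries here. With the erythroid score in the fit they kept 1.04 of that, and after removing the trend with exonic length 0.92 (201 of the 203 with a length). Neither the score nor that trend took up most of the fitted change. The genes were chosen on these same libraries, which inflates their size and favours a high share kept. Red cell content and transcript length are therefore not excluded as causes. Without the 1 library whose loss lowered it most they kept 0.94, which decides nothing for the same reason. RNA quality also stays open: the authors' calls include mt-Co3 (0.88), mt-Nd6 (0.65), Malat1 (1.17) and Neat1 (0.86), all higher, and mitochondrial genes took 2.61 ± 0.827% of the values in WDF and 1.92 ± 0.394% in WD males. A shared litter or dissection day stays open, as does the maternal diet, and the labels used here give neither litter nor day.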

How the results depend on the processing

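Settings chosen only after the results were seen are library weights, fits without 2, 3 or 4 libraries, trimmed-mean scaling, pseudocounts of 0.5 and 5, residual components, and the looser threshold for the authors' tables. The planned DESeq2 and svaseq alternatives were not run, since the values are not counts. Counts stayed at 0 in the 8 comparisons between 2 groups and the 5 differences of effects with upper-quartile and trimmed-mean scaling, no or a stricter filter, limma-voom, the replicate block, pseudocounts of 0.5 and 5, a threshold of 0.1, 38, 37 or 36 libraries, and without any 1 of the 40 libraries (0 to 0). They also stayed at 0 in a fit of the 20 libraries of 1 sex, run only where a comparison lies within that sex. Recomputed median-ratio factors were 1 and test nothing. The sex count ran from 7 to 12 outside the residual components and from 9 to 10 without 1 library, and with the block within diet it was 7, as Kdm6a (adjusted p = 0.143) and 5530601H04Rik (0.0812) no longer passed. With a threshold of 1.5-fold, Eif2s3x (log2 difference 0.56) and 5530601H04Rik (0.45) were too small to be counted. In 0 of 12 checks of equal replicate numbers did every pair of libraries correlate over 0.1 (range -0.53 to 0.65). At most 2 libraries correlated best with their own number. For WDF males and females, however, 4 of 5 pairs correlated over 0.1. The replicate block left the sex count at 9 and the other counts at 0. Such checks cannot exclude a shared dam, so whether the numbers pair the libraries stays open.

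Library weights, which count libraries far from their group less, gave 514 genes for folic acid in WD males, 93 for the western diet at 2 mg/kg and 293 at 10 mg/kg in males, 603 for folic acid by sex on the western diet and 351 for folic acid by diet in males. With the compared groups alone they gave 648, 48 and 504 in the same 3 male comparisons and 1 (Amy2a3) in females at 2 mg/kg. In females, weights with the compared groups alone and the 2 libraries left out gave 1 (Fabp2) for folic acid on the control diet and 1 (Amy2a3) for the western diet at 2 mg/kg. The compared groups alone, unweighted, gave 1 (Amy2a3) for the latter, with and without the 2 libraries. An erythroid score as covariate gave 1 for the western diet at 2 mg/kg in males with 40 and with 38 libraries, and 1 (Hps4) for folic acid in WD males with 38. The cause of these moves was not tested. Of the 110 gene results, 108 kept their direction outside the residual components. Pnpla3 in females at 2 mg/kg went from 0.12 to -0.89 without CD replicate 4 (also with 38 and 37 libraries, the compared groups or 18 females without the 2 libraries, and both residual settings with 38), -1.04 with 36, -1.21 and -0.77 with the erythroid score (40 and 38), -1.01, -1.05 and -1.09 with weights, -0.14 with a pseudocount of 5 and -0.04 without WD replicate 1; without 1 library it ran from -0.89 to 0.45. Klf1 there went to -0.15 with the erythroid score, which is built from such genes.

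Calls of lists over the 8 comparisons between 2 groups numbered 81, and 0 with an estimated correlation, 0 with fry, 82 with the block, 90 with the erythroid score, 85 with 38 and 80 with 36 libraries. The list of ribosomal proteins in females at 10 mg/kg turned from Down to Up without CDF replicate 4 (median 0.09; from -0.50 to 0.09 without 1 library), and that of red cells in females at 2 mg/kg turned from Up to Down with the erythroid score built from it (median 0.01). The authors' deposited tables gave 14 genes in place of 7 in CD males and 382 in place of 203 in WD males at an adjusted p under 0.1.

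Residual components were computed after the group means were taken out. They cannot alter the estimated differences and only shrink the spread, so their counts are no evidence of change; they are given because they were tried. Component 1 with 40 libraries gave 3937 for the western diet at 2 mg/kg and 1243 at 10 mg/kg in females, 1560 for sex and 1404 for the western diet by sex. Components 1 and 2 gave, for folic acid in CD males, CD females, WD males and WD females, 338, 2599, 1129 and 516; for the western diet at 2 mg/kg in males and females 476 and 6902, and at 10 mg/kg 1233 and 3514; for sex 3090; and for the differences of effects 3100, 2199, 2512, 3376 and 5247. With 38 libraries, component 1 gave in the same order 274, 2658, 1236 and 482; 430, 1478, 1268 and 2412; and 3385, 2216, 2556, 3632 and 2012. Both components gave 627, 3137, 1622 and 726; 747, 2177, 1669 and 2887; 28 for sex; and 3809, 2665, 3107, 4115 and 2498. With 5 libraries per group and the spread of the 38 libraries, a 1.5-fold change was recovered for 26.9% of simulated genes in WDF against WD males, so small effects would mostly be missed. Larger ones may be missed too in the 40-library fit, whose spread is wider.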

Other observations

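The splits and the test of opposite effects were planned before their results were seen, but the weighted counts come from a setting chosen afterwards, and the wording for 1 of the tests, the 35 splits, was changed after its result was seen. In WDF against WD males, 8 further lists were called by camera, 7 of them higher. Genes of oxidative phosphorylation were higher in 27 of 29 (median log2 difference 0.31, adjusted p = 0.00024) and ribosomal protein genes in 34 of 38 (0.21, 0.00828). Immediate early genes were higher in 13 of 15 (0.30, 0.00398), with Fos, a fast-response transcription factor, at 46.8 ± 21.7 against 22.6 ± 9.2. Interferon response genes were higher in 18 of 23 (0.29, 0.0163), skeletal muscle markers in 11 of 13 (0.63, 0.0432), drug and steroid metabolism in 18 of 21 (0.27, 0.0451) and gluconeogenesis in 16 of 20 (0.28, 0.0451). Genes of the unfolded protein response were lower in 19 of 26 (-0.14, 0.0451). With an estimated correlation each of the 8 gave adjusted p = 0.899. The ribosomal call was lost without WD replicate 4 (median 0.09) or 5 (0.11; 0.34 without 2), the interferon call without WD replicate 2 (0.13) or 3 (0.12; 0.49 without 4), and the metabolism call without WD replicate 1 (0.34), 2 (0.26) or 3 (0.20) or WDF replicate 1 (0.23). The gluconeogenesis call was lost without WD replicate 1 (0.22), 2 (0.24) or 3 (0.29) or WDF replicate 1 (0.26), 2 (0.26) or 4 (0.29). The muscle call was lost without WD replicate 1 (0.67), 3 (0.61), 4 (0.56) or 5 (0.43) or WDF replicate 1 (0.46), 2 (0.35) or 4 (0.47), and with the erythroid score as a covariate (0.56), and its median was 1.08 without WDF replicate 3 and 1.20 without 5. The oxidative phosphorylation call was kept, with 0.15 without WD replicate 5. The unfolded protein call was lost without WD replicate 1 (-0.12), 2 (-0.17) or 3 (-0.12) or WDF replicate 1 (-0.16) or 5 (-0.09), and with the erythroid score, and its median was -0.23 without WD replicate 4 and -0.27 without 5. Abhd5, which activates triglyceride breakdown, averaged 1840 ± 255 in WDF and 3300 ± 575 in CDF males.

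Lists called by camera with 40 and with 38 libraries for the western diet, beyond those in the results above, were these. In WDF against CDF males, immediate early genes were higher in 14 of 15 (median log2 difference 0.35, or 0.21 without CDF replicate 2, adjusted p = 0.00179) and ribosomal protein genes in 38 of 38 (0.25, 0.00021), with an estimated correlation adjusted p = 0.985. In WD against CD females, oxidative phosphorylation was higher in 29 of 29 (0.58, and 0.29 with 38 libraries), ribosomal proteins in 36 of 38 (0.45, then 0.35) and unfolded protein genes in 22 of 26 (0.41, then 0.18), with an estimated correlation adjusted p = 0.637. The last call was lost with the erythroid score (0.01) and with 36 libraries (0.13). In WDF against CDF females, cell cycle genes were higher in 29 of 30 (0.37, then 0.15) and genes of the insulin axis in 17 of 22 (0.21, then 0.16), and ribosomal proteins lower in 36 of 38 (-0.27, then -0.50), with an estimated correlation adjusted p = 0.546, 0.546 and 0.566. The cell cycle call was lost without CDF replicate 5 (0.15), with 36 libraries (0.07) and with the erythroid score (0.02), the insulin call without CDF replicate 4 (0.15) or 5 (0.16) and with 36 libraries (0.04), and the ribosomal median turned to 0.09 without CDF replicate 4 and was -0.50 without CDF replicate 5 and -0.16 without WDF replicate 4.

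Between the sexes, megakaryocyte markers were lower in females in 15 of 15 cases (median log2 difference -0.51, -0.16 with 38 libraries, -0.32 and -0.30 without the CD or the CDF low-albumin library, and -0.06 with 36, where the call was lost) and markers of stellate and mesenchymal cells higher in 15 of 22 (0.42, then 0.17). With an estimated correlation both gave adjusted p = 0.534 with 40 libraries. Xist was 10.67, 7.649 and 10.72 in WDF males replicates 3, 4 and 5 and at most 1.334 in the other 17 males. Among females it was 648.3 in CDF replicate 4 and 3029 or more in the others. That CDF library also had the highest sum of values of all 40 (27817171) and the highest Hba-a1 (1516000). Without it the ribosomal call for folic acid in control diet females was lost (median 0.10, from 0.41). The oxidative phosphorylation median there fell from 0.47 to 0.23. The ribosomal median in WDF against CDF females turned from -0.27 to 0.09. Why this library stands apart was not tested.

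Other splits of the same libraries tested whether the grouping itself gave the counts. For the 13 contrasts with 0 genes, 100 of 100 splits gave as many by definition, so only the highest other counts say anything. The highest other counts were 5821 for folic acid in CD females, 2544 for the western diet at 10 mg/kg in females, 1980 for folic acid by sex on the control diet and 6301 for folic acid by diet in females. Counts that far above the real 0 point to a structure of the samples, and the cause was not tested. All of these but the western diet at 10 mg/kg regrouped CD with CDF females. Such splits could put both low-albumin libraries on the same side, whereas the real grouping has 1 on each side. For the other 9 contrasts the highest was 4 or less. They include the western diet effect at 2 mg/kg in females and by sex, which use CD females replicate 4 but not CDF females replicate 5. For sex, 1 of 100 splits, the real one, gave as many as 9 genes (highest other 1), so chance is excluded.

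Counts at an unadjusted p under 0.05 with 38 libraries were reached by other splits too, so chance is not excluded for any of the 8. For folic acid, 38 of 100 splits gave as many as the real 536 in CD males (highest other 3404), 17 of 35 as many as 1196 in CD females (4571), 9 of 100 as many as 1354 in WD males (2497) and 64 of 100 as many as 221 in WD females (5508). For the western diet at 2 mg/kg, 23 of 100 gave as many as 1023 in males (4966) and 10 of 100 as many as 1011 in females (3593), and at 10 mg/kg 9 of 100 as many as 1061 in males (2307) and 29 of 100 as many as 1252 in females (5724). With library weights, 1 of 100 splits, the real one, gave as many as 514 genes for folic acid in WD males (highest other 77), 4 of 100 as many as 293 for the western diet at 10 mg/kg in males (2432) and 2 of 100 as many as 351 for folic acid by diet in males (1017). Few other splits reached those 3 counts, each taken singly. Chance is still not excluded for them, since the weights were chosen after the data were seen and fetuses may share litters. More splits reached the 93 genes of the western diet at 2 mg/kg in males (10 of 100, highest other 2770) and the 603 of folic acid by sex on the western diet (16 of 100, 6130). These 5 were picked because the weights gave calls there, with no correction for that choice.

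A hypothesis was that the high folic acid dose may move the livers of western diet males back toward the control diet, since Ccnb1, Phf19 and Pms2 were higher in WD than in CD males and lower in WDF than in WD males. Both effects use the same 5 WD libraries, which alone gives them opposite signs. Over 15598 genes the covariance of the effects was -0.102 with the shared libraries and -0.0389 with the WD libraries split so that none was in both, which is 0.38 of the unsplit size. Of 100 regroupings of the 15 libraries, 11 gave a split covariance as low, the real one included, so neither the reversal nor the shared libraries alone can be told apart from the other with 5 libraries per group. The lipid synthesis lists did not follow this pattern, as Me1 and Acly were low in WDF as well as in WD males.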
